A study of Arabidopsis thaliana with 64 samples.

How the data were processed

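RNA from Arabidopsis thaliana roots was hybridised to Affymetrix arrays with 22810 probe sets, 1 array per sample. Per the labels, total RNA was extracted with Trizol and labelled with biotin as the manufacturer recommends. The deposited values are intensities on a linear scale, 1 summary value per probe set and array. The software, its version and the background step are not given in the sources used here. The values themselves show that the authors scaled each array, since the mean over probe sets with the lowest and highest 2% left out is 500 on every array. No shared distribution was imposed. Array medians therefore ranged from an intensity of 103 to 303, or 6.70 to 8.25 on the log2 scale.

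The labels place 64 arrays in 32 groups of 2, which hold every combination of 5 signals, each present or absent. Groups and doses were taken from the labels. The labels number the arrays of a group as replicates 1 and 2 but do not say that they came from separate cultures. The p-values then measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Correlations of duplicate arrays across probe sets ranged from 0.724 to 0.897, with a median of 0.846, and the median correlation between arrays of different groups was 0.83. Probe sets are not independent replicates. No pair of arrays held identical values.

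The 64 control probe sets were left out of the tests and 22746 probe sets were tested. Intensities were transformed as log2(value + 1), with a pseudocount of 1. A fold change is thus on the log2(value + pseudocount) scale, which understates the change of genes with low intensity. No filter on dim probe sets was applied. Group means of all 32 groups were fitted with limma 3.58.1 in R 4.3.3, and empirical Bayes moderation gave a prior of 3.83 degrees of freedom beside 32 residual ones. The Benjamini-Hochberg adjustment was applied within each comparison, and a probe set passed at an adjusted p under 0.05. All adjusted p-values for single genes below come from this fit.

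The effect of a signal was its mean difference over the 16 combinations of the other 4 signals, 32 arrays against 32. In 8 of the 16 combinations adding nitrate or ammonium also lowered the other ion from 1 to 0.5 mM and gave the added ion at 0.5 mM, so the averaged effects of both ions and their counts carry this change of dose. Each signal alone was also set against the mock group, 2 arrays against 2. The interaction of a pair of signals was the difference between the effect of one with and without the other, averaged over 8 combinations. A moderated F test covered the interactions of 3 or more signals. Nitrate without ammonium was set against ammonium without nitrate over the 8 hormone combinations, 16 arrays against 16. The fit was tested on simulated data with the spread of these arrays and 50 probe sets changed at each size. The simulated noise was normal and independent between probe sets, without array-wide shifts. Recovery and false calls on the real arrays may therefore differ. For the averaged IAA effect it recovered 20% of changes of 0.5 on the log2 scale, 52% of changes of 1 and 100% of changes of 2, with 6 false calls. For IAA alone against mock it recovered 0% of changes of 1, 12% of changes of 2 and 40% of changes of 3. For the interaction of IAA with ABA it recovered 10% of changes of 1, 66% of changes of 2 and 92% of changes of 3, with 3 false calls.

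Probe sets were named through the annotation table of the array platform, which gives 1 gene for 13513 probe sets, several for 503 and no entry for 8794. Of the first, 13436 matched the RefSeq gene table of assembly TAIR10.1, which was used for names only. Coverage was uneven. Genes with a name of their own had a named probe set in 14.6% of cases, and genes known by locus tag only in 63.1%. Probe sets without a name stayed in every test and count.

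The tests, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. For each averaged effect the rule took the 8 largest increases and the 8 largest decreases among named probe sets that passed, and members of the lists. It took the 3 largest in each direction for every other comparison. A gene with several probe sets was to be represented by the one with the highest mean, and no gene named under the rule had several. Of the lists, the nitrate response list had 3 of its 27 genes named on the array, the auxin response list 7 of 29, the cytokinin response list 4 of 26, the ABA response list 2 of 31, the iron acquisition list 2 of 11, the root hair list 2 of 8 and the green tissue list 2 of 20. The lists for ammonium uptake and assimilation, ethylene, phosphate starvation and the cell cycle had 0 named members and could not be tested here. Other members of a list may be on the array without a name here. They would then count among the probe sets the list was compared with. Because coverage was this low, 34 gene families that share a symbol stem and the chloroplast-encoded genes were added after the annotation was seen. All but the LEA stem had 8 genes or more and were added before their results were seen. The LEA stem, with 5 genes, was added after the genes with the largest changes had been seen, so its set test was left out.

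Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, and adjusted over the 35 tests of 7 lists and 5 effects. The 170 tests of the families other than the LEA stem were adjusted separately. Array medians and the ratios of 3' to 5' control probe sets were compared between arrays by permutation tests with 100000 resamples, kept within combinations of the other factors and adjusted over 24 tests. The mean log2 ratios were 4.47 for actin, 8.70 for GAPDH and 3.60 for ubiquitin without ABA, and 4.47, 8.41 and 3.74 with it. The 3' set was brighter than the 5' set on every array, a bias that may limit every value. The other settings fixed beforehand were quantile normalization, removal of the dimmest 40% of probe sets, pseudocounts of 16 and 64, a replicate block, array weights, a trended and robust prior, a model of single signals and pairs on all arrays and on those of each replicate number, and the omission of each array in turn. After the data had been seen, 3 more were added: the array median as a covariate, the actin ratio as a covariate, and omission of the 6 arrays with the most extreme medians. Responses of whole sets were also compared after quantile normalization, over the probe sets that had passed as deposited and over those that passed after that step. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.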

Results

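Roots of Arabidopsis were profiled after 4 h on media that held any combination of 5 signals. These were nitrate and ammonium, the inorganic nitrogen sources of plants, and the hormones indole-3-acetic acid (IAA, an auxin), kinetin (a cytokinin) and abscisic acid (ABA, a stress hormone). The design asked how roots respond to combinations of nitrogen and hormonal signals. Plants had grown with ammonium succinate and then spent a day without nitrogen. Nitrate and ammonium were each given at 1 mM, or at 0.5 mM each when both were present. IAA and kinetin were given at 500 nM and ABA at 1 µM, and potassium chloride and DMSO served as mock treatments. Each of the 32 groups had 2 arrays. Changes below are log2 differences ± SE, averaged over the 16 combinations of the other signals, 32 arrays against 32, unless stated otherwise. In 8 of these 16 combinations adding one ion also lowered the other to 0.5 mM, and the averaged nitrate and ammonium effects carry that change of dose.

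Nitrate raised AT5G10210 by 3.26 ± 0.25 (adjusted p = 1.58e-11) and AT1G49500 by 2.72 ± 0.20 (adjusted p = 2.74e-12), both in 16 of 16 backgrounds. AT5G62720 rose by 2.22 and AT3G25790 (HHO1), which encodes a transcription factor of the nitrate-responsive HRS1 family, rose by 1.85, each in 16 of 16 backgrounds. AT1G80380, a glycerate kinase, rose by 1.92, AT4G33960 by 1.94, the glutaredoxin AT4G15690 by 1.95 and the bHLH gene AT1G68240 by 1.95. The organic cation and carnitine transporter OCT1 fell by 1.99 on the log2 scale in 16 of 16 backgrounds, AT1G78990 fell by 1.55, the FCS-like zinc finger gene AT1G22160 fell by 1.51 and its relative AT4G17670 was 2.82-fold lower. The glutaredoxin AT4G33040 fell by 1.44, and AT5G04120 and TBL21 were each 2.46-fold lower. AT3G57630 fell by 1.38 (adjusted p = 0.0342), a call lost when any 1 of 27 arrays was left out. With a pseudocount of 64 the changes of AT4G15690 (0.94), AT1G68240 (0.76), OCT1 (-1.29), AT1G78990 (-0.78), AT3G57630 (-0.69) and TBL21 (-0.61) were smaller by over 1.5 times and still passed.

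Of the 3 named members of the nitrate response list, 2 rose. PGD1, an enzyme of the oxidative pentose phosphate pathway, rose by 1.07 ± 0.10 (adjusted p = 1.41e-09, 16 of 16 backgrounds), and HHO3 rose by 0.60 ± 0.13 (adjusted p = 0.0131, 14 of 16). HHO2 stood at 0.56 ± 0.19 (adjusted p = 0.244) and passed with the array median as a covariate and with a replicate block. Adjusted over the list alone, 3 rose. The list stood above the other probe sets (camera adjusted p = 9.64e-10, and 3.15e-06 with an estimated correlation). In all, 201 probe sets passed in limma, of which 124 rose and 77 fell, and 74 changed at least 2-fold. With the array median as a covariate 348 passed, 175 up and 173 down. With the actin ratio as a covariate HHO3 (0.54 ± 0.14), AT3G57630 (2.45-fold lower) and AT5G04120 (-1.34 ± 0.34) no longer passed, although their changes stayed about as large. AT5G04120 did not pass without the 6 arrays of extreme median either (-0.96 ± 0.33).

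Ammonium raised AT1G30820, a CTP synthase, by 1.18 ± 0.14 (adjusted p = 1.34e-06, 15 of 16 backgrounds) and AT3G45730 by 1.37 ± 0.18 (adjusted p = 1.33e-05, 14 of 16). AT1G47400 (IRON MAN 1), a peptide of the iron deficiency response, rose by 1.27 ± 0.22 (adjusted p = 0.00103). AT1G33813 rose by 1.45, AT1G72060 by 1.43, AT5G56100 by 1.33, AT5G22320 by 1.27 and scpl31 by 1.19. AT3G14395 fell by 1.33, the PR1-like gene AT4G33720 fell by 1.23 and the glutaredoxins AT3G62960 and AT1G06830 fell by 1.08 and 0.79. AT4G17670, which also fell with nitrate, fell by 0.99 ± 0.14 (adjusted p = 9.33e-05). AT1G55790 fell by 0.88, AT1G04330 fell by 0.77 and AT3G02910 fell by 0.89. The calls of AT3G02910 and AT5G22320 were lost when any 1 of 38 and 35 arrays was left out. No member of the ammonium list was named on the array. In all, 115 probe sets passed, of which 84 rose and 31 fell, and 34 changed at least 2-fold. With the array median as a covariate 193 passed, 120 up and 73 down, and without the dimmest 40% of probe sets 178 passed. Without the 6 arrays of extreme median AT1G33813 (1.35), AT1G72060 (1.17), scpl31 (1.13), AT4G33720 (-1.07), AT3G02910 (-0.71) and AT1G06830 (-0.79) no longer passed, and AT5G22320 did not pass with array weights, in the model of pairs or with the actin ratio as a covariate (1.26 ± 0.31). With a pseudocount of 64 the changes were 0.46 for AT1G33813, which did not pass, 0.55 for AT5G22320 and 0.73 for scpl31.

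Nitrate as the nitrogen source was compared with ammonium at the same total nitrogen. AT5G10210 was higher on nitrate by 2.95 ± 0.36 (adjusted p = 1.69e-06), AT3G25790 by 2.50 ± 0.24 (adjusted p = 2.22e-08) and AT3G14395 by 2.42 ± 0.40 (adjusted p = 0.000579). OCT1 was lower on nitrate, with a difference of -2.74 ± 0.46 (adjusted p = 0.000745), as were AT1G47400, at -1.73 ± 0.31 (adjusted p = 0.0017), and AT5G43450, at -1.68 ± 0.25 (adjusted p = 0.000107). Of 16 arrays against 16, 89 probe sets passed, 55 higher and 34 lower on nitrate, and with the array median as a covariate 198 passed. OCT1 stood at -1.63 with a pseudocount of 64.

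IAA raised GH3.3, which conjugates auxin to amino acids, by 6.53 ± 0.24 (92.4-fold, adjusted p = 1.76e-21, 16 of 16 backgrounds). Its mean log2 intensity without IAA was 5.59, below the lowest array median of 6.70. The exact fold is therefore uncertain, as background levels are unknown. The same limit holds for AT5G10210 without nitrate (6.09) and COR15A without ABA (6.61), but not for ARR16 without kinetin (8.68). LBD29, a transcription factor of lateral root initiation, rose by 3.82 ± 0.28 (adjusted p = 1.3e-12), and the peptide gene CLE44 rose by 2.80 ± 0.17 (adjusted p = 1.04e-14). AT4G37295 rose by 3.68, AT4G21740 by 3.15, AT3G09280 by 3.05 and AT5G62280 by 2.59. AT5G66815 (CEP5), a peptide gene, fell by 2.51 ± 0.29 (adjusted p = 7.37e-08), AT3G59370 fell by 2.16 and the peroxidase AT2G39040 was 4.58-fold lower. The dirigent-like genes AT4G11190 and AT4G11210 fell by 2.14 and 2.09, AT3G43960 fell by 1.79, AT1G19900 fell by 1.77 and the glutaredoxin AT4G15690, which rose with nitrate, fell by 1.70. With a pseudocount of 64 the changes of AT4G21740 (1.58), AT5G62280 (1.11), AT2G39040 (-1.35) and AT4G15690 (-0.80) were smaller by over 1.5 times and still passed.

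Of the 7 named members of the auxin response list, 5 rose with IAA. They were GH3.3, LBD29, the Aux/IAA gene IAA29 at 2.65 ± 0.28, GH3.1 at 2.55 ± 0.27 and GH3.5 at 0.96 ± 0.13. LBD16 stood at 0.07 ± 0.21 (adjusted p = 0.947) and IAA20 at -0.12 ± 0.28 (adjusted p = 0.931), and neither value kept its sign under every alternative. At a pseudocount of 64 IAA29 rose by 1.56 and GH3.1 by 1.07. Adjusted over the list alone, 5 rose, and the list stood above the other probe sets (camera adjusted p = 3.68e-23, and 2.53e-08 with an estimated correlation). The cytokinin response regulator ARR16 fell by 0.80 ± 0.15 (adjusted p = 0.00101). EXPA18, an expansin of root hairs, fell by 0.68 ± 0.13 (adjusted p = 0.00126), and EXPA7 stood at -0.24 ± 0.11 (adjusted p = 0.376). The root hair list of these 2 genes stood below the other probe sets (camera adjusted p = 0.00931), with an adjusted p = 0.111 with an estimated correlation. Adjusted over the list alone, 2 fell.

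In all, 603 probe sets passed for IAA, of which 288 rose and 315 fell, and 199 changed at least 2-fold. With the array median as a covariate 1123 passed. With the actin ratio as a covariate 410 passed, 345 of them among the 603. This ratio of 3' to 5' probe sets of the actin control, a sign of RNA quality, was higher with IAA by 0.37 on the log2 scale (adjusted permutation p = 0.00756), and this stands beside each gene group given for IAA. The ratios of the GAPDH and ubiquitin controls were not higher with IAA (-0.17 and -0.088, adjusted permutation p = 0.845 for both). Whether RNA quality differed with IAA is therefore not settled by these controls.

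**Figure D1:**
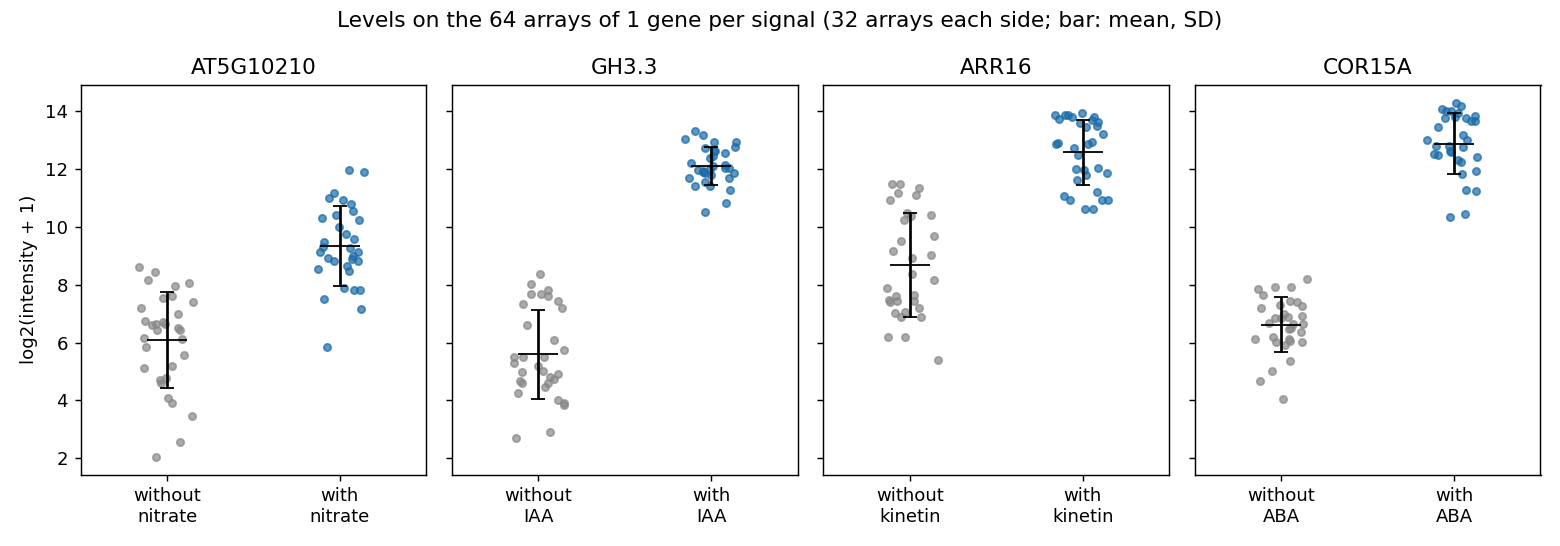
Log2 intensity (y axis) of AT5G10210 without and with nitrate, GH3.3 without and with IAA, ARR16 without and with kinetin and COR15A without and with ABA, 1 point per array (n = 32 per side), with the mean and SD. GH3.3 rose from a mean of 5.59 to 12.12 and its 2 sets of arrays did not overlap, as 8.39 was the highest value without IAA and 10.50 the lowest with it.

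Kinetin raised ARR16, a negative regulator of cytokinin signalling, by 3.90 ± 0.15 (adjusted p = 3.89e-20) and the dirigent-like genes AT4G11190 and AT4G11210 by 4.02 ± 0.28 (adjusted p = 3.69e-13) and 2.69 ± 0.28 (adjusted p = 1.17e-08), all in 16 of 16 backgrounds. AT4G35725 rose by 3.76, AT1G34330 by 3.00, AT5G47980 by 2.89, AT5G26620 by 2.88 and AT1G66800 by 2.58. OCT1 fell by 2.42 ± 0.33 (adjusted p = 2.4e-06, 16 of 16 backgrounds), as it did with nitrate. AT2G02630 fell by 1.46, AT3G22540 fell by 1.37, the peroxidase AT3G01190 fell by 1.37, AT1G07690 fell by 1.29, AT1G15640 fell by 1.21 and AT5G04730 fell by 1.20. AT1G33930 fell by 1.29 (12 of 16 backgrounds) but stood at -0.21 among the replicate 2 arrays, where it did not pass. With the actin ratio as a covariate AT1G33930 (-1.07 ± 0.34) and AT5G04730 (-1.12 ± 0.32) no longer passed, although their changes stayed about as large. With a pseudocount of 64 the changes were smaller by over 1.5 times for AT1G34330 (1.22), OCT1 (-1.58), AT2G02630 (-0.83), AT5G04730 (-0.73) and AT1G33930 (-0.46), which alone did not pass.

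Of the 4 named members of the cytokinin response list, ARR16 and ARR15 rose with kinetin, ARR15 by 2.49 ± 0.30 (adjusted p = 2.19e-07). The cytokinin glucosyltransferases UGT76C1 and UGT76C2 stood at -0.29 ± 0.24 and -0.06 ± 0.20 (adjusted p = 0.863 and 0.998). Adjusted over the list alone, 2 rose, and the list stood above the other probe sets (camera adjusted p = 2.38e-08, and 1.01e-05 with an estimated correlation). In all, 470 probe sets passed, of which 298 rose and 172 fell, and 179 changed at least 2-fold. With the array median as a covariate 742 passed.

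ABA raised the late embryogenesis abundant (LEA) gene AT3G02480 by 9.18 ± 0.29 (adjusted p = 2.51e-24), LEA4-5 by 8.33 ± 0.23 (adjusted p = 1.58e-26) and the cold and drought gene COR15A by 6.28 ± 0.25 (adjusted p = 1.02e-21), all in 16 of 16 backgrounds. AT4G31830 rose by 7.81, AT1G16850 by 7.40, AT2G21820 by 6.55, AT2G38905 by 6.38 and AT5G66780 by 6.16. AT1G07680 fell by 4.15 ± 0.31 (adjusted p = 1.83e-13) and the receptor-like kinase AT5G37450 fell by 3.80 ± 0.27 (adjusted p = 7.49e-14). AT1G70985 fell by 3.52, AT4G21870 was 11.3-fold lower, AT4G07820 fell by 3.09, AT2G23440 fell by 3.06, AT4G12360 fell by 3.01 and the glutaredoxin AT1G06830 fell by 3.00. With a pseudocount of 64 the decreases of AT5G37450, AT1G70985 (-2.10) and AT2G23440 (-1.43) were smaller by over 1.5 times and still passed.

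Both named members of the ABA response list rose, COR15A and the dehydrin COR47, which rose by 3.42 ± 0.12 (adjusted p = 2.54e-23). Adjusted over the list alone, 2 rose, and the list stood above the other probe sets (camera adjusted p = 1.41e-09, and 3.24e-06 with an estimated correlation). Of the 5 genes of the LEA stem, 3 rose, among them LEA18 by 4.11 ± 0.28 (adjusted p = 1.35e-14). This stem was chosen after the largest changes with ABA had been seen, so that no set test of it is read here. Of 11 genes of the ATG stem, which act in autophagy, 6 rose, with ATG8H the largest at 1.27 ± 0.14 (adjusted p = 5.11e-09). The ATG genes had a camera adjusted p = 0.000201, but an adjusted p = 0.816 with an estimated correlation. Their median was 0.36, with 0.32 after quantile normalization and 0.39 with the array median as a covariate, and 6 rose under each. The median of the LEA genes was 0.98, with 1.19 and 0.77 under the same settings, where 3 rose under each and 1 fell with the covariate.

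Members of other lists also changed with ABA. PGD1 of the nitrate list fell by 0.95 ± 0.10 (adjusted p = 9.56e-10), and F6H1, which makes iron-mobilising coumarins, fell by 1.41 ± 0.11 (adjusted p = 3.19e-13). ARR16 rose by 2.51 ± 0.15 and ARR15 fell by 1.54 ± 0.30 (adjusted p = 7.16e-16 and 0.00012). IAA29 fell by 0.88 and LBD16 fell by 0.71, and neither passed with the array median as a covariate (-0.61 and -0.51), nor IAA29 without the 6 arrays of extreme median (-0.75). The root hair genes EXPA7 and EXPA18 fell by 0.51 and 0.47 (adjusted p = 0.000724 and 0.00735). Among markers of green tissue, LHCB4.1, a chlorophyll-binding protein, rose by 0.84 ± 0.25 (adjusted p = 0.00906) in 11 of 16 backgrounds and RCA stood at -0.05 ± 0.17 (adjusted p = 0.859). At a pseudocount of 64 IAA29 stood at -0.50, ARR15 at -0.96 and LHCB4.1 at 0.52, and all 3 passed. Against the other probe sets none of these lists passed with ABA, with camera adjusted p = 0.514 for nitrate, 0.689 for auxin, 0.268 for cytokinin, 0.13 for iron, 0.261 for root hair and 0.411 for green tissue.

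In all, 6210 probe sets passed for ABA, or 27.3% of those tested. Of these 1929 rose and 4281 fell, while among the 1781 that changed at least 2-fold, 827 rose and 954 fell. The median of all probe sets lay at -0.19, so that small changes are relative to that shift. After quantile normalization 5561 passed, 2568 up and 2993 down, and with the array median as a covariate 6642 passed, 2740 up and 3902 down. The median log2 intensity of an array differed by -0.18 with ABA (permutation p = 0.0247, adjusted p = 0.119).

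**Figure D2:**
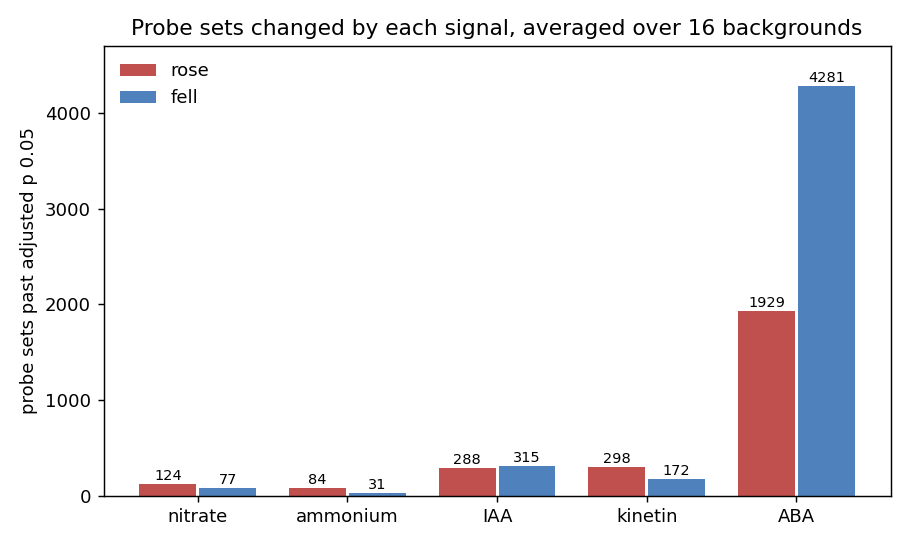
Number of probe sets that rose and that fell (bars, from 0) at an adjusted p under 0.05 for each of the 5 signals, averaged over 16 backgrounds (32 arrays against 32). ABA has 1929 up and 4281 down, and ammonium the fewest, 84 up and 31 down.

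Each signal alone was also compared with mock, 2 arrays against 2. Nitrate alone raised AT5G10210 by 5.54 ± 1.01, AT1G80380 by 4.97 ± 0.75 and AT1G49500 by 4.53 ± 0.78 (adjusted p = 0.00865, 0.00221 and 0.00604). The glutaredoxins AT5G11930 and AT4G33040 fell by 3.76 ± 0.75 and 2.84 ± 0.45, and AT1G64590 fell by 2.01 ± 0.37 (adjusted p = 0.0214, 0.00221 and 0.011). IAA alone raised GH3.3 by 7.08 ± 0.96, LBD29 by 5.54 ± 1.11 and AT4G37295 by 4.52 ± 0.83 (adjusted p = 0.000124, 0.0378 and 0.0173). Kinetin alone raised ARR16 by 5.35 ± 0.61 (adjusted p = 5.18e-06). ABA alone raised AT3G02480 by 11.03 ± 1.17, AT1G16850 by 9.05 ± 0.96 and AT4G31830 by 8.69 ± 0.70 (adjusted p = 8.05e-08, 8.05e-08 and 1.91e-10). AT2G23440 fell by 7.23 ± 1.45, AT1G70985 fell by 5.56 ± 1.26 and AT3G48710 fell by 5.42 ± 1.38 (adjusted p = 0.00337, 0.0128 and 0.0359).

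Against mock, 19 probe sets passed for nitrate (16 up), 2 for ammonium, both up and without a gene name here, 10 for IAA, all up, 4 for kinetin, all up and 3 of them without a name, and 278 for ABA (204 up, 74 down). Without mock replicate 2 these counts were 1 for nitrate, 4 for IAA, 2 for kinetin and 139 for ABA, and GH3.3 did not pass (adjusted p = 0.052). Without mock replicate 1, kinetin had 9 and ABA 170. Leaving out nitrate replicate 1 or 2 gave 11 or 12, IAA replicate 1 or 2 gave 5 or 6, ABA replicate 1 or 2 gave 114 or 159, and ammonium replicate 1 or 2 gave 1 or 0 by limma, against 688 at an unadjusted p under 0.05 on all arrays. The 688 is fewer than a share of 0.05 of the 22746 probe sets tested, which chance alone would give. With the actin ratio as a covariate 2 passed for IAA. LBD29, at 5.83 ± 1.41, and AT4G37295, at 4.00 ± 1.04, were not among them, as the changes stayed about as large and the SE grew from 1.11 and 0.83. AT5G10210, AT5G11930 and AT1G64590 did not pass without any 1 of the 4 arrays of nitrate and mock, AT1G49500 without mock replicate 2 or either nitrate array, AT1G80380 without mock replicate 1 (3.01) and AT4G33040 without mock replicate 2 (-2.89). LBD29 did not pass without any 1 of 9 arrays or without the 6 arrays of extreme median, AT4G37295 without any 1 of the 4 of IAA and mock, and AT2G23440 and AT1G70985 without mock replicate 2 or ABA replicate 1. AT3G48710 did not pass without any 1 of the 4 of ABA and mock, with the array median as a covariate (-4.63) or without the 6 arrays (-5.42). Its size depended on the pseudocount, at -3.01 with 16 and -1.55 with 64, and it passed with neither. With 64, AT4G31830 stood at 5.51, AT2G23440 at -4.53 and AT1G70985 at -3.66, and these passed.

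The effect of one signal was then compared with and without another. AT1G15600 changed with IAA by 0.28 ± 0.18 without kinetin and by 2.65 ± 0.18 with it, a difference of 2.37 ± 0.26 (adjusted p = 1.8e-06, 8 of 8 backgrounds). AT4G35725 changed with kinetin by 2.28 ± 0.39 without ABA and by 5.24 ± 0.39 with it, a difference of 2.96 ± 0.55 (adjusted p = 0.0496, 8 of 8), a call lost when any 1 of 44 arrays was left out. With ABA the effect of IAA on the tetraspanin TET12 went from 0.38 to -2.73, a difference of -3.11 ± 0.56 (adjusted p = 0.00978). The differences were -2.50 ± 0.40 for AT2G28690 (adjusted p = 0.0029) and -2.31 ± 0.36 for AT3G55720 (adjusted p = 0.00199). For MSRB9, a methionine sulfoxide reductase, the effect of IAA went from -0.91 to 0.91, a difference of 1.81 ± 0.27 (adjusted p = 0.00135). AT4G28820 changed with nitrate by -0.36 ± 0.15 without ammonium and by 0.81 ± 0.15 with it (difference 1.17 ± 0.21, adjusted p = 0.0221), which is confounded with the halved dose of both ions. It did not pass after quantile normalization, in the model of pairs or with the actin ratio as a covariate (2.15-fold), nor without nitrate replicate 2 (1.14), without replicate 1 of nitrate with IAA and kinetin (1.14) or without replicate 1 of nitrate with ammonium and ABA (1.14). AT3G55720 was dim, with mean log2 intensities of 4.39 to 6.53, and with a pseudocount of 64 its difference was -0.94 and that of TET12 -1.80, and both passed. AT4G28820 (1.07), TET12 (-2.52) and AT4G35725 (2.65) did not pass without the 6 arrays of extreme median, and none of these 7 genes passed among the 32 arrays of replicate 1 or of replicate 2 taken alone. With fewer arrays the differences kept their direction, at 2.65 and 2.09 for AT1G15600, -2.76 and -3.46 for TET12, and 1.44 and 2.19 for MSRB9 in replicates 1 and 2. They stood at -1.81 and -3.19 for AT2G28690, -2.04 and -2.58 for AT3G55720 and 2.78 and 3.14 for AT4G35725, while AT4G28820 stood at 1.04 in replicate 2 and higher in replicate 1.

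**Figure D3:**
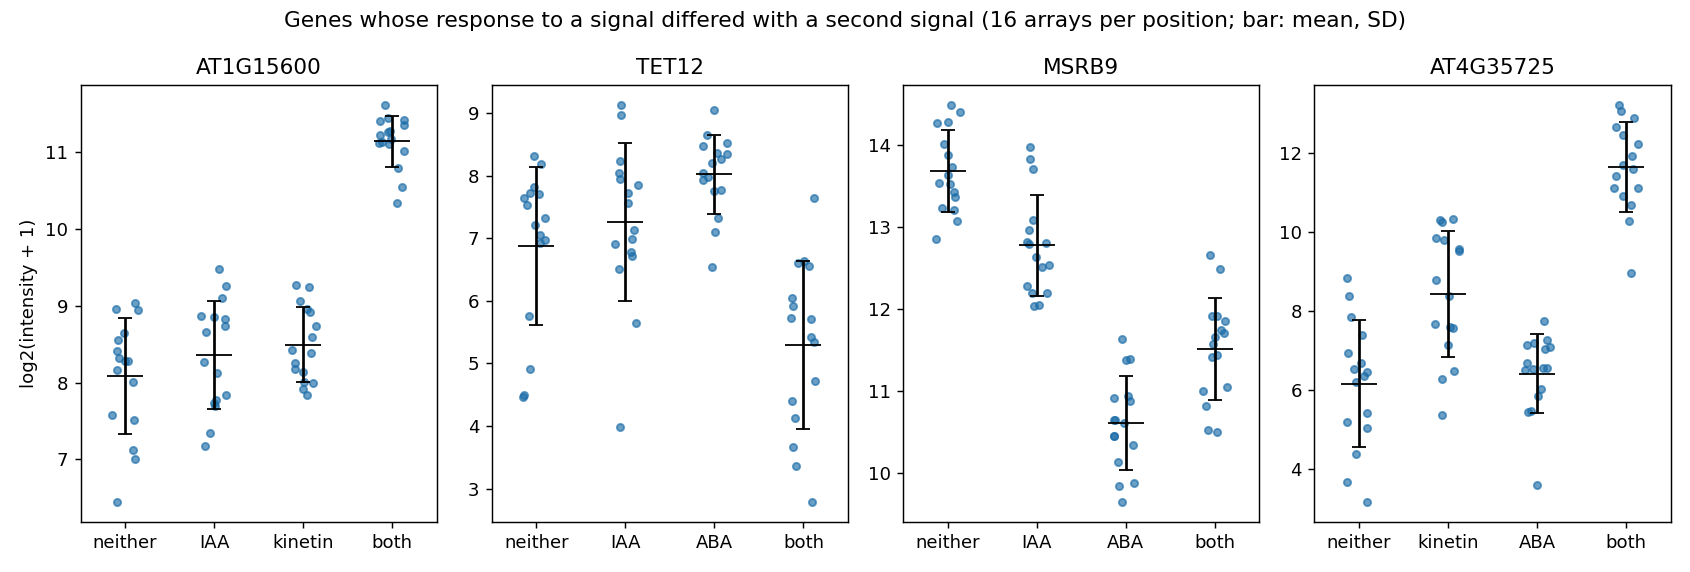
Log2 intensity (y axis) of AT1G15600, TET12, MSRB9 and AT4G35725 with neither, one or both of the 2 signals named on each panel, 1 point per array (n = 16 per column), with the mean and SD. AT1G15600 had a mean of 11.14 with IAA and kinetin, against 8.08, 8.36 and 8.50 with neither, IAA or kinetin.

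In limma 9 probe sets passed for IAA with ABA (1 up, 8 down), 3 for nitrate with ammonium (2 up, 1 down), 2 for IAA with kinetin and 2 for kinetin with ABA, both up in each. Other settings gave kinetin with ABA more calls in both directions, 4 up and 4 down after quantile normalization, 12 up and 5 down with a pseudocount of 64 and 4 up and 3 down in the model of pairs. For IAA with kinetin the model of pairs gave 3 up and 1 down. For nitrate with IAA 0 passed in limma, against 662 at an unadjusted p under 0.05, for nitrate with ABA 0 against 925, for ammonium with IAA 0 against 815, for ammonium with kinetin 0 against 828 and for ammonium with ABA 0 against 697. For nitrate with kinetin 0 passed in limma against 3141 at an unadjusted p under 0.05, with a smallest adjusted p of 0.0914, and for interactions of 3 or more signals 0 passed against 748. Chance alone would give a share of 0.05 of the 22746 probe sets at that threshold, and of these counts only the 3141 lies above it. The median difference of all probe sets for nitrate with kinetin lay at 0.24, so that small differences there are relative to that shift.

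The response of whole sets was compared too, by tests chosen after the counts of interactions had been seen. Each probe set that passed for a signal was given the sign of its change, and the mean response of the set was compared with and without a second signal over 8 backgrounds, by a two-sided exact sign-flip test adjusted over 20 tests. The 201 probe sets of nitrate, OCT1 and AT5G10210 among them, had a mean response of 1.15 ± 0.25 (SD, n = 8 backgrounds) without ABA and 0.81 ± 0.07 with it, lower in 8 of 8 backgrounds (exact p = 0.00781, adjusted p = 0.0391). In the backgrounds without ammonium the response was 1.25 to 1.43 without ABA and 0.77 to 0.91 with it. In those with ammonium, where nitrate was at 0.5 mM, it was 0.91 to 0.97 without ABA and 0.74 to 0.78 with it. The 115 probe sets of ammonium had 1.04 ± 0.28 without ABA and 0.69 ± 0.17 with it (SD, n = 8), also lower in 8 of 8 (exact p = 0.00781, adjusted p = 0.0391). The nitrate response kept 75.4% of its size with ammonium, and the ammonium response 72.8% with nitrate, each lower in 8 of 8 backgrounds (adjusted p = 0.0391), where the dose was also halved. After quantile normalization of the same probe sets both still passed (adjusted p = 0.0391), while over the 150 probe sets called for ammonium after that step, 107 of them among the 115, the ammonium response with nitrate did not (adjusted p = 0.134). The 603 probe sets of IAA had 1.05 ± 0.09 without ABA and 0.90 ± 0.10 with it, lower in 7 of 8 backgrounds (exact p = 0.0156, adjusted p = 0.0625). After quantile normalization the same 603 again had an adjusted p = 0.0625, and the 687 called after that step, 550 of them among the 603, had 0.0391. The 470 probe sets of kinetin had 0.98 ± 0.08 without ABA and 1.02 ± 0.09 with it (exact p = 0.438, adjusted p = 0.673). The smallest p that 8 backgrounds allow is 0.00781, and the remaining tests did not pass.

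**Figure D4:**
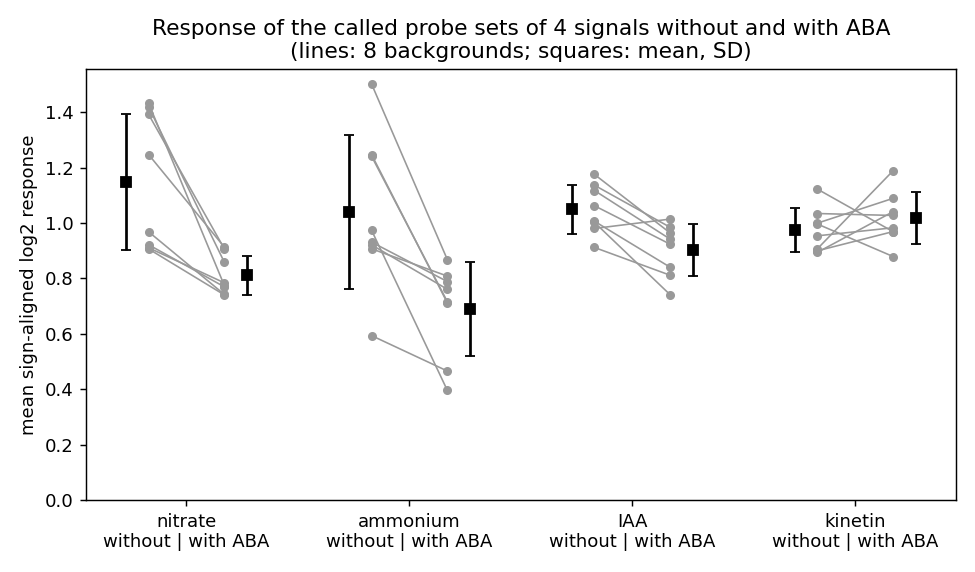
Mean sign-aligned log2 response (y axis, from 0) of the probe sets that passed for nitrate, ammonium, IAA and kinetin, without and with ABA, 1 line per background (n = 8) and squares for the mean and SD. The nitrate and ammonium responses were lower with ABA in 8 of 8 backgrounds, the IAA response in 7 and the kinetin response in 3.

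Across lists, 5 of the 35 tests passed with camera at the preset correlation, and 4 with the correlation estimated. The 5 were the nitrate, auxin, cytokinin and ABA response lists, each with its own signal, and the root hair list with IAA. The ammonium list could not be tested. With nitrate, the cytokinin list had a camera adjusted p = 0.0585, iron 0.223, root hair 0.744, green tissue 0.891, auxin 0.9 and ABA 0.538. The median, mean and direction of the test differed in sign for the auxin list with nitrate and for the iron list with IAA, neither of which passed. Of the 170 tests of families chosen before their results were seen 3 passed at the preset correlation and 0 with it estimated, while fry called 16. They were ATG with ABA and the VPS genes of vesicle sorting with IAA and nitrate, for which 1 and 0 of 14 genes passed in limma. The VPS genes had camera adjusted p = 0.0166 with IAA and 0.0317 with nitrate, and adjusted p = 0.932 for both with an estimated correlation.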

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

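The comparisons of whole sets with a second signal, the weighing of signal range for all sets and of scaling for the nitrate and ammonium sets, the repeat of the set comparisons on quantile-normalized values, and the repeat of the kinetin splits after quantile normalization were tests chosen after the result was seen. For 1 other test the rule for reading the value was tightened after the value was known, and for the IAA set a test of signal range set beforehand was replaced, as stated with each. A first test of scaling for ABA, the share rising after quantile normalization (46.2%), was dropped because that step balances the split by construction.

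The effect of 1 signal differed with another for few probe sets. The counts were 3 for nitrate with ammonium, 2 for IAA with kinetin, 9 for IAA with ABA and 2 for kinetin with ABA. AT4G28820 differed by 1.17 in its response to nitrate when ammonium was present, at halved doses of both. AT1G15600 differed by 2.37 in its response to IAA when kinetin was present. With ABA present the response to IAA differed by 1.81 for MSRB9, by -3.11 for TET12, by -2.50 for AT2G28690 and by -2.31 for AT3G55720. AT4G35725 differed by 2.96 in its response to kinetin when ABA was present. Probe sets without a gene name here differed by -1.40 and 1.47 for nitrate with ammonium, by 1.59 for IAA with kinetin and by 3.85 for kinetin with ABA, and these 4 were chosen after their values were seen. Of the control probe sets, which were left out of the tests of genes, 2 of 64 changed with ABA, the ubiquitin 3' set by 0.49 (adjusted p = 1.96e-05) and an actin 3' set by -0.32 (adjusted p = 0.0446). Both kept their direction after quantile normalization (0.45 and -0.39) and with the array median as a covariate (0.48 and -0.17), where the actin set did not pass.

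Responses of whole sets also differed. The nitrate set differed by -0.28 with ammonium and the ammonium set by -0.27 with nitrate, where the dose is confounded with the second ion.

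The first pattern weighed is the smaller response of the nitrate set (-0.34) and of the ammonium set (-0.35) with ABA. The decrease of the nitrate set was larger in each background without ammonium, at 1 mM nitrate, than in those with it, at 0.5 mM. A compressed signal range on ABA arrays is argued against by the kinetin set, whose mean response with ABA was 104% of that without it, with a lower 95% bound of 92.3%. As the mean of the shares kept in each of 8 backgrounds it kept 105%, against 72.6% for the nitrate set and 68.5% for the ammonium set. The differences were 32.6 percentage points (exact permutation p = 0.000155, the smallest that 8 and 8 backgrounds can give) and 36.6 (exact p = 0.000466). These shares come from the same arrays but were permuted as independent values, so the p-values are descriptive only. As ratios of mean responses, the upper 95% bounds were 85.5% for nitrate and 85.3% for ammonium, below the kinetin bound. The comparison with kinetin was chosen after the responses had been seen, and the nitrate, ammonium and IAA sets all kept less. A shift in log2 level shared by all ABA arrays cancels in these responses, so quantile normalization is no test of it. Other differences in the distribution of values between arrays are argued against by that step. After it the same probe sets differed by -0.38 for nitrate and -0.37 for ammonium. The 67 nitrate and 40 ammonium probe sets not called for ABA differed by -0.34 and -0.37 (exact sign-flip p = 0.00781 in both), so the lower response was not limited to probe sets called for ABA. Probe sets that were not called can still be moved by ABA, so a response limited to genes that ABA itself moves stays open. That ABA lowers the response of roots to both nitrogen sources is one hypothesis these values are consistent with, found and tested on the same arrays, and uptake of the ions was not measured.

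The second pattern is the response of the IAA set, which differed by -0.15 with ABA (exact p = 0.0156, adjusted p = 0.0625). That ABA damps the IAA response as a whole was predicted to give a value below 0 with an exact p under 0.05, and this was met before adjustment and not after it. A compressed signal range on ABA arrays as the whole cause is argued against here too, since by the mean of these shares the kinetin set kept 105% of its response with ABA and the IAA set 86.2%, a difference of 18.9 percentage points (exact permutation p = 0.00653, and 0.00264 for the same probe sets after quantile normalization), although all sets come from the same arrays. The test set beforehand asked only whether the kinetin or the nitrate set was at or above 0 with ABA, which the kinetin set met at 0.042, within its SD of 0.14 over 8 backgrounds. After quantile normalization the same 603 probe sets differed by -0.18 (adjusted p = 0.0625) and the 687 called anew by -0.17 (adjusted p = 0.0391), so whether the IAA response as a whole is lower with ABA stays open.

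The third pattern is the excess of falling probe sets with ABA (4281 against 1929). A difference in array-wide scale would lower the bacterial hybridization controls, and the mean of these 18 probe sets differed by -0.15 with ABA (permutation p = 0.502). This meets the size set beforehand, but the spread between arrays was 0.89 (SD), and the demand for a p under 0.05 was added after the value was seen, so scale cannot be told apart from a change in the roots. Lower RNA integrity was tested by the 3' to 5' ratios of 3 controls. Their differences with ABA were 0.00064 for actin, -0.29 for GAPDH and 0.14 for ubiquitin (adjusted permutation p = 0.995, 0.72 and 0.72). The median, 0.00064, met neither bound set beforehand. With the actin ratio as a covariate 6170 of the 6210 probe sets passed in the same direction. As that ratio differed by only 0.00064 with ABA, the covariate could hardly move these changes, and the count decides nothing here. Lower RNA integrity as a whole stays open as well. A true excess of decreases in the roots remains among the open explanations.

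Whether other groupings of the arrays give as many calls was tested with 100 splits for each result, the real one included. For nitrate (201 calls against at most 3 in the other splits), ammonium (115 against 5) and IAA (603 against 2), 1 of 100 splits, the real one, gave as many. So it was for ABA (6210 against 2) and nitrate against ammonium as source (89 against 2). A chance split of single arrays can be excluded for these at the 0.05 level. All splits moved single arrays, as if duplicates were separate cultures, which the labels do not say. Chance differences between cultures that duplicates share are thus not excluded for any result. For nitrate with ammonium (3 against 2), IAA with kinetin (2 against 1) and IAA with ABA (9 against 1) the real split alone gave as many. Each split shuffled 1 signal of the pair and so removed its averaged effect too. Chance is therefore not excluded for these interactions. For kinetin 2 of 100 splits gave as many as the real 470, and the other gave 1211. Such a count may come from a structure of the samples, but none was identified. This split had the largest difference in array medians of those drawn (0.23), but after quantile normalization it still gave 455, against 513 for the real split, so the medians alone do not account for it, and no other structure was tested. After that step 1 of 100 gave as many, the real one. For kinetin with ABA 2 of 100 gave as many, with 2 calls against at most 2 in the other splits. These 2 shares are under 0.05 too, but for kinetin with ABA chance is not excluded, as for the other interactions.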

How the results depend on the processing

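The array median and the actin ratio as covariates and the omission of 6 arrays of extreme median (5 high, 1 low) were tests chosen after the result was seen, and the other alternatives were planned. Counts for averaged effects stayed within 1.5 times under array weights, the trended prior, quantile normalization, the model of pairs, a pseudocount of 16 and the omission of any array. With 2 arrays per group both arrays of a group received the same weight. Array weights thus weigh groups and cannot mark a single poor array. Counts that did not are given here, and the cause was not tested except where fewer samples or probe sets explain it. The planned repeat with each probe set of a gene gave no value, as no named gene had several. Dim probe sets limit the precision, since background levels are unknown.

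Without the dimmest 40% of probe sets 178 passed for ammonium, 30 for nitrate alone, 8 for kinetin alone and 5 for kinetin with ABA. Quantile normalization gave 1 for ammonium alone, 8 for kinetin alone, 1 for nitrate with ammonium, 1 for ammonium with ABA and 8 for kinetin with ABA. Array weights gave 65 for nitrate alone, 5 for ammonium alone, 9 for kinetin alone and 6 for kinetin with ABA. The trended and robust prior gave 29, 4, 8 and 7 for the same 4 results. The model of pairs gave 1 for ammonium with ABA, 4 for IAA with kinetin and 7 for kinetin with ABA. A pseudocount of 16 gave 1 for ammonium with ABA and 6 for kinetin with ABA. A pseudocount of 64 gave 177 for ammonium, 31 for nitrate alone, 15 for kinetin alone, 2 for nitrate with ABA, 1 for ammonium with ABA and 17 for kinetin with ABA, and lowered 35 of 131 changes of named genes by over 1.5 times, of which 3 no longer passed. For lists, fry gave 12 calls against 5.

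With the array median as a covariate 348 passed for nitrate, 193 for ammonium, 1123 for IAA, 742 for kinetin, 6 for ammonium alone, 16 for IAA alone, 9 for kinetin alone, 5 for nitrate with ammonium, 5 for IAA with kinetin, 8 for kinetin with ABA and 198 for nitrate against ammonium as source. The actin ratio as a covariate gave 2 for IAA alone and 4 for kinetin with ABA. Without the 6 arrays 4 passed for ammonium alone and 5 for IAA with ABA.

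The replicate numbers were not taken to pair the samples, since the labels do not say whether a number marks a batch and deviations of same-numbered arrays correlated by -0.26 to 0.42 over 496 pairs of groups, with 164 over 0.1. A replicate block gave 173 for ammonium, 1 for nitrate with ABA, 16 for IAA with ABA and 6 for kinetin with ABA, and moved no other count by over 1.5 times. In replicate 2 array medians were higher by 0.22 (adjusted permutation p = 0.0341), and so were the log2 ratios of 3' to 5' probe sets of the GAPDH and ubiquitin controls, by 1.19 and 0.49 (adjusted p = 0.00756 and 0.0341), so a batch is not excluded. HHO2 passed with nitrate under the block (adjusted p = 0.0351), within a range of 0.0332 to 0.677 over its 13 other settings, and no other named result that had passed or not was moved across the threshold by the block.

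With the 32 arrays of replicate 1 the model of pairs gave 87 for nitrate, 27 for ammonium, 382 for IAA, 298 for kinetin, 3769 for ABA, 19 for nitrate against ammonium as source and 1 for ammonium with ABA. In limma it gave 0 for nitrate with ammonium, IAA with kinetin, IAA with ABA and kinetin with ABA. With replicate 2 it gave 74, 35, 160 and 220 for the first 4, 27 for the source, 1 for nitrate with ammonium, 1 for nitrate with kinetin, 2 for nitrate with ABA, 1 for IAA with kinetin, and 0 for IAA with ABA and kinetin with ABA. Fewer samples enter these. Of 115 results for named genes, 36 and 37 were then no longer past the threshold and 2 and 0 changed sign.

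Leaving out each array in turn gave 1 to 25 for nitrate alone, 0 to 3 for ammonium alone, 4 to 12 for IAA alone, 2 to 9 for kinetin alone, 114 to 295 for ABA alone, 1 to 6 for nitrate with ammonium, 0 to 3 for nitrate with kinetin, 0 to 1 for nitrate with ABA, 0 to 1 for ammonium with kinetin, 0 to 2 for ammonium with ABA, 2 to 5 for IAA with kinetin, 7 to 15 for IAA with ABA (15 without replicate 1 of ammonium with IAA), 1 to 5 for kinetin with ABA (moved by 43 of 64 arrays) and 0 to 2 for 3 or more signals. The lone array of a group is then assumed to vary like the other groups. The averaged effects ranged from 170 to 231 for nitrate, 99 to 170 for ammonium, 542 to 665 for IAA, 436 to 499 for kinetin and 5795 to 6694 for ABA. Of 8384 values of named genes, 8193 kept direction and side of the threshold, 186 no longer passed and 5 changed sign.

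Values that changed sign had not passed. LBD16 with IAA stood at -0.00040 among the replicate 1 arrays, and from -0.050 to 0.19 with 1 array left out. IAA20 with IAA stood at 0.064 among the replicate 1 arrays and 0.082 with the actin ratio, and from -0.25 to 0.014 with 1 array left out. UGT76C2 with kinetin ranged from -0.18 to 0.062.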

Other observations

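The tests of shared direction and the tally of signals per probe set were chosen after the result was seen.

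Several named genes responded to more than 1 signal. The dirigent-like genes AT4G11190 and AT4G11210 rose with kinetin, by 4.02 and 2.69, and fell by 2.14 and 2.09 with IAA. OCT1 fell by 1.99 with nitrate and fell by 2.42 with kinetin, and it rose with ABA by 2.82 ± 0.33 (adjusted p = 1.1e-08). ARR16 rose with kinetin (3.90) and with ABA (2.51) and fell by 0.80 with IAA, while ARR15 rose with kinetin (2.49) and fell by 1.54 with ABA. Of the 22746 probe sets 16078 passed for 0 of the 5 averaged effects, 5899 for 1, 618 for 2, 140 for 3, 11 for 4 and 0 for 5, each from limma. The 4 named genes that passed for 4 signals were AT1G58170, AT1G64590, AT2G15960 and AT5G43450, and they were chosen after their values were seen. AT1G58170 rose with kinetin (1.37) and ABA (1.52), fell by 0.61 with nitrate and fell by 0.54 with ammonium. AT5G43450 rose with IAA (1.78), ABA (1.02) and ammonium (0.78) and fell by 0.90 with nitrate.

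Of the 25 probe sets that passed for both nitrate and ammonium, 24 changed in the same direction, 10 up and 14 down (two-sided Fisher's exact p = 3.37e-06, adjusted over 10 tests 3.37e-05). Of the 347 that passed for IAA and ABA, 224 changed in the same direction (adjusted p = 0.000136), 168 of them down. Of the 134 that passed for nitrate and ABA, 89 changed in opposite directions (adjusted p = 0.0021). The 107 of IAA and kinetin changed in the same direction in 46 cases (adjusted p = 0.729). Probe sets are not independent, and all effects share 1 estimate of the spread, so the number that passed for both of a pair was not read as a shared response.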
